A study of Mus musculus with 4 samples.

How the data were processed

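RNA was measured by sequencing in 4 libraries of cartilage from mouse forelimbs of the C57BL/6 strain. Per the labels' protocols, chondrocytes were cut out of cryosections by laser microdissection. PC stands for proliferating chondrocytes at embryonic day 14.5 (replicates 1 and 2), and HC for hypertrophic chondrocytes at embryonic day 15.5 (replicates 3 and 4). The labels' protocols name a column kit for small amounts of RNA, and a library kit for degraded RNA that was used with mouse primers. How the cells of each zone were recognised is not given in the sources used here.

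Per the submitters' processing notes, the authors used Trimmomatic 0.36, a read trimmer, kallisto 0.43.1, which assigns reads to transcripts without aligning them to the genome, and the mouse build mm10. The deposited tables list, per the file headers, an estimated count, a TPM value (transcript abundance on a common scale), a length and an effective length for each transcript. Estimated counts are shares of reads assigned by likelihood among transcripts that hold the same sequence, so they need not be whole. The strand setting and the bootstraps of that step are not given in the sources used here. Antisense and overlapping genes may therefore share reads, and the assignment error of a single transcript is unknown. TPM, as deposited, is scaled to transcript length and to a fixed total, so it keeps no depth. Reads of near-identical copies, such as the replication-dependent histones, the haemoglobin genes and the gene model Gm10800, are split by the same estimate, and values of such genes are uncertain.

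The tables held 109282 transcripts, of which 107987 matched the GENCODE M21 annotation (GRCm38) by identifier without version and 1295 did not. Matched transcripts made 34547 genes, and 82 of them share a symbol with another gene. Coordinates are those of that annotation, counted from 1. Unmatched transcripts held 0.53%, 0.53%, 0.36% and 0.4% of the estimated counts of PC replicates 1 and 2 and HC replicates 3 and 4, and stayed out of the tests.

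Estimated counts were summed per gene and rounded to whole numbers. Genes were kept with filterByExpr of edgeR 4.0.16, which left 16607, and scaled with the trimmed mean of M values (TMM), whose factors were 1.14, 1.058, 0.812 and 1.021 in the same order. The main test was edgeR's quasi-likelihood F-test of HC against PC, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene is said to have risen, fallen or passed only on that test. CPM values are counts scaled to a common library size with the TMM factors. The standard error (SE) of a log2 fold change was derived from the fitted coefficient and the F statistic. For genes with no count in HC a lower bound on the fold is given against a floor of 3 counts over the group. For genes with 1 to 3 counts the ratio is given with its exact Clopper-Pearson 95% interval. Bounds and intervals cover counting error only, since amplified reads are not independent molecules.

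A test against a 2-fold change used glmTreat in the same fit. Gene lists were tested with camera at a preset correlation of 0.01 between genes, two-sided, and adjusted over 38 lists with at least 5 genes tested. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. At the preset correlation camera treats genes as nearly independent units, so its p-values can be too small. With an estimated correlation it rests on the 2 residual degrees of freedom. For prehypertrophic genes the estimated correlation was 0.001, below the preset, yet the unadjusted camera p went from 2.21e-09 to 0.0234. Not passing in that form is therefore little evidence against a list. Transcript usage within a gene was tested with diffSpliceDGE on transcript counts, with Simes p-values per gene. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were used, with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 for summing, permutation tests and plots.

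The 38 lists and the rule for named genes were fixed before the data were examined. The lists cover cartilage matrix, prehypertrophic, hypertrophic and mineralisation genes, S phase, mitosis and histones, and Hedgehog, Wnt, BMP and TGF-beta, and FGF signalling. They also cover glycolysis, oxidative phosphorylation, secretion, proteases, sulphation, 4 lists of chromatin regulators, limb patterning, ribosomal proteins, mitochondrial genes, immediate early genes, cholesterol, autophagy, apoptosis and cilium genes. Further lists hold markers of osteoblasts, perichondrium, joint, muscle, endothelium, red blood cells, macrophages, osteoclasts, epidermis and nerve. Of 986 distinct symbols, 4 matched no gene. Named in each direction are the 10 protein-coding genes with the largest change among those that passed, with a mean TPM of at least 10 in the higher group, no overlap between groups and a symbol that is not a predicted model. Up to 4 members with the lowest adjusted p are named from each list, and 22 genes of the growth plate and of chromatin are named whatever their value. For transcript usage, Col2a1, Runx2, Sox5, Fn1 and the 5 genes with the lowest adjusted p and a mean of at least 100 counts per library are named. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

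Total estimated counts were 30373440 and 36644496 in PC and 15246529 and 21866266 in HC. With 2 libraries per group, 2 residual degrees of freedom remained. On simulated counts for the real genes with 200 of them changed, run on 16010 genes, the test recovered 16% of 4-fold, 52% of 8-fold, 64% of 16-fold and 74% of 32-fold changes. It called 113 genes, of which 10 were unchanged, and none on data without changes. In the real data 4492 genes had an unadjusted p under 0.05 with edgeR. The adjustment depends on the share of changed genes, so these rates do not give the power of the real test. The same simulation of transcript usage, run on 8372 genes at the real noise, recovered 1% of 8-fold drops and called 71 unchanged genes, against 80% and 7 at a dispersion of 0.05.

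Age differs between the groups exactly as cell type does, so no term for age could be fitted. The groups share no replicate number. The labels do not tie captured pieces to animals, so p-values measure the spread between these samples, which may be technical. If pieces of 1 group came from the same animal, p-values are too small. Alternatives fixed beforehand were DESeq2 size factors, library size alone, upper-quartile factors, no filter, a minimum of 50 counts, transcript length as an offset, protein-coding nuclear genes only, a robust prior, DESeq2, limma-voom, limma-trend on log2(TPM + 1) of genes with a mean TPM of at least 1, a threshold of 0.01, and leaving out each library. A fit without 1 library takes its noise from the 1 pair that remains, so a gene that passes only there gains no support. A threshold of 0.1 was added after seeing the data.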

Results

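Gene expression was compared between proliferating chondrocytes (PC) of mouse forelimb cartilage at day E14.5 of development and hypertrophic chondrocytes (HC) at E15.5, with 2 libraries each. The series concerns the epigenetic control of the step from one state to the other, in which cells of the growth plate stop dividing and enlarge. Libraries held between 15246529 and 36644496 estimated counts, and both HC libraries were shallower than both PC libraries. Any count was found for 21352 and 21154 genes in PC and for 17012 and 17945 genes in HC. Mitochondrial transcripts took 8.86% and 13.22% of counts in PC and 20.23% and 14.17% in HC. Effective minus annotated length of longer transcripts had medians of -172.8 and -153.3 in PC and -124.7 and -145.5 in HC. Values nearer to 0 go with shorter fragments, so RNA quality may differ between the groups, which was not tested. HC replicate 3 stood apart from the other libraries in the share of Gm10800, a gene model chosen after its values were seen, at 8.78% against 1.76% to 2.68%. The 2 tables of a group were not copies of 1 library, since the chi-square of their counts per degree of freedom was 114 in PC and 219 in HC.

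In HC, the secreted signal Ihh, the transcription factor Mef2c, the phosphatase Alpl and the growth factors Bmp2 and Bmp6 rose. The transcription factors Sox5, Sox8 and Gli1, the mitotic kinase Aurka and 11 of 30 replication-dependent histone genes tested fell. Of 16607 genes tested, 457 were higher and 325 lower in HC with edgeR's quasi-likelihood test. The median fold was 8.4 among the higher and 5.4 among the lower genes. The smallest adjusted p was 0.0359, so many large differences lay just to either side of the threshold, and 4492 genes had an unadjusted p under 0.05. Without single libraries 379 to 3331 genes were higher and 257 to 3775 lower, the most without HC replicate 4. No gene passed the edgeR test against a 2-fold change. All 782 genes that passed had both libraries of one group above both of the other, as had 61% of the genes tested, against 33.3% by chance. Scaling to library size alone, which shifted the median of all genes to -0.29 on the log2 scale, ended every call (0 genes, 4394 at an unadjusted p under 0.05), as did limma-trend on TPM (0 genes, 3594 at an unadjusted p under 0.05).

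Among the genes with the largest rise, Ihh (chromosome 1, 74945315 to 74951672) had 36.3 and 56.6 CPM in PC and 3501 and 583 CPM in HC. Its log2 fold change was 5.46 ± 0.97 (SE, n = 2 per group, edgeR adjusted p = 0.043), and 3.62 without HC replicate 3. Cd55, a regulator of complement, rose from 4.39 and 17.9 to 658 and 421 CPM, a log2 fold change of 5.60 ± 0.80 (edgeR adjusted p = 0.0359), and 4.88 without PC replicate 1 and 6.909 without PC replicate 2. The receptor tyrosine kinase Ephb1 rose by 5.59 ± 0.69 and the prostaglandin-degrading enzyme Hpgd by 5.55 ± 1.0 on the same scale. Pde11a, Plk2, Irx5, Ddit4l and Ntn4 rose by 5.38, 5.28, 5.26, 5.25 and 5.20. These 7 genes, in the order named, had 4.978, 4.715, 4.566, 4.537, 4.51, 4.417 and 4.604 without PC replicate 1 and 6.565, 7.475, 7.189, 6.71, 6.757, 7.218 and 6.124 without PC replicate 2. Myh3, an embryonic muscle myosin, also rose, by 5.56 ± 0.90, with 113 CPM in HC replicate 3 and 27.6 in HC replicate 4, and by 4.172 without HC replicate 3.

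Among the genes with the largest fall, Hist1h3h had 2533 counts in PC and 0 in HC, at least 399.6-fold lower, and Ninj2 had 342 and 0, at least 54.0-fold lower. Cmtm5 was 491-fold lower (95% counting interval 136 to 4056, from 2 counts in HC), Ppp1r36 481-fold lower (86 to 19012, from 1 count) and Hist1h4i 149-fold lower (26 to 5889, from 1 count). Reads of histone genes are split by estimate among near-identical copies, so the values of Hist1h3h, Hist1h4i and Hist1h2bg are uncertain. The bound and interval for Hist1h3h and Hist1h4i do not cover that split. Gli1 (chromosome 10, 127329882 to 127341974), a target and effector of Hedgehog signalling, had 43.7 and 26 CPM in PC and 0.243 and 0.675 in HC, a log2 fold change of -6.14 ± 0.64. Sox8, a relative of Sox9, had 170 and 112 CPM in PC and 2.84 and 3.29 in HC, a change of -5.51 ± 0.40 (edgeR adjusted p = 0.0359). Hist1h2bg, Trabd2b and Scrg1 changed by -5.57, -5.42 and -4.97. Without HC replicate 4 Hist1h2bg was at -8.406 and Gli1 at -7.181, and without PC replicate 1 Scrg1 was at -4.245. The calls of Ninj2 and Hist1h4i were lost without PC replicate 1 (edgeR adjusted p = 0.535 and 0.758), and that of Hist1h4i without PC replicate 2 (0.0794).

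The main markers of the chondrocyte state did not all pass. Col2a1 and Acan, the main collagen and proteoglycan of cartilage, did not pass, with log2 fold changes of -0.36 ± 0.47 and -0.54 ± 0.49 (edgeR adjusted p = 0.67 and 0.54). Acan had -0.20 without HC replicate 3 and -1.08 without HC replicate 4, and Col2a1 had -0.10 without PC replicate 1, -0.64 without PC replicate 2 and -0.55 without HC replicate 4, none of which passed. Sox5, a partner of Sox9, fell from 308 and 290 to 52 and 37.4 CPM (-2.75 ± 0.33, edgeR adjusted p = 0.0359). Sox9, Sox6 and Fgfr3 had changes of -1.69 ± 0.47, -1.30 ± 0.29 and -1.69 ± 0.39 that did not pass (edgeR adjusted p = 0.0947, 0.0614 and 0.0698). Sox9 passed without PC replicate 2, HC replicate 3 (-2.43) or HC replicate 4 (-1.27), Fgfr3 without PC replicate 2 (-2.06), HC replicate 3 or HC replicate 4, and Sox6 without HC replicate 3 or HC replicate 4. Of 28 cartilage matrix and chondrocyte core genes, 5 fell, 0 rose and 23 did not pass, and adjusted over the list alone 15 fell and 1 rose. Besides Sox5 and Scrg1, those that fell were Matn4, a matrix protein (-3.79), Wwp2 (-2.65) and Prelp (-3.68), which was chosen after its values were seen. The list's median was -1.37 (camera adjusted p = 6.07e-08, and adjusted p = 0.365 with an estimated correlation). Without single libraries 8 to 18 members were lower.

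Of 19 prehypertrophic genes 7 rose, 1 fell and 11 did not pass, and adjusted over the list alone 13 rose and 2 fell. The median of the list was 1.40 (camera adjusted p = 1.2e-08, and adjusted p = 0.359 with an estimated correlation). Mef2c, which drives hypertrophy, rose from 136 and 215 to 1340 and 1690 CPM (3.11 ± 0.41, edgeR adjusted p = 0.0359). Bmp6 and Bmp2 rose by 4.13 ± 0.50 and 3.14 ± 0.38, and Pth1r, the receptor of parathyroid hormone-related protein, by 2.29 ± 0.41. Runx3 fell (-2.01 ± 0.31). Runx2 was at 154 and 172 CPM in PC and 370 and 697 in HC, which did not pass (1.71 ± 0.40, edgeR adjusted p = 0.0705) but did without HC replicate 3 (2.07) or HC replicate 4 (1.14), and Sp7 and Cdkn1c differed by 0.58 ± 0.38 and 0.23 ± 0.39. Cdkn1c turned to -0.06 with scaling to library size alone and to -0.10 without HC replicate 3, with 0.05 without PC replicate 1, 0.36 without PC replicate 2 and 0.43 without HC replicate 4. Sp7 had 0.86 without PC replicate 1, 0.28 without PC replicate 2, 0.83 without HC replicate 3 and 0.17 without HC replicate 4.

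Several hypertrophic markers had a wide gap between the PC libraries. Col10a1 (chromosome 10, 34389981 to 34397085), the collagen of the hypertrophic zone, had 109 and 876 CPM in PC and 17800 and 26920 in HC. Its log2 fold change of 5.50 ± 1.12 did not pass (edgeR adjusted p = 0.0538). Mmp13, Ibsp and Spp1 had changes of 5.20 ± 1.24, 5.26 ± 1.30 and 5.01 ± 1.29, which did not pass either (edgeR adjusted p = 0.0716, 0.0762 and 0.0822). Col10a1, Mmp13, Ibsp and Spp1 were at 4.64, 4.26, 4.33 and 4.07 without PC replicate 1 and 7.65, 8.05, 8.14 and 7.93 without PC replicate 2. In PC replicate 2, Col10a1, Mmp13 and Ibsp stood 8.0, 13.8 and 14.0 times above PC replicate 1, and Spp1 had 280 CPM against 19.3. Of 25 hypertrophic genes, 17 of which are also in other lists, 6 rose and 0 fell, and adjusted over the list alone 19 rose and 1 fell. Without single libraries 12 to 21 were higher. Those that rose include the phosphate regulator Phex (4.65 ± 0.70), Alpl (4.56 ± 0.69), the pyrophosphate transporter Ank (2.99 ± 0.37) and the cell cycle inhibitor Cdkn1a (3.03 ± 0.42). Phex and Alpl were at 3.97 and 3.87 without PC replicate 1 and 5.798 and 5.767 without PC replicate 2, and Cdkn1a at 2.44 without HC replicate 4. The list's median was 2.99 (camera adjusted p = 7.76e-13, and adjusted p = 0.359 with an estimated correlation). Vegfa did not pass, at 1.77 ± 0.51 (edgeR adjusted p = 0.0987), with 0.82 without HC replicate 4 and 2.29 without HC replicate 3.

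**Figure D1:**
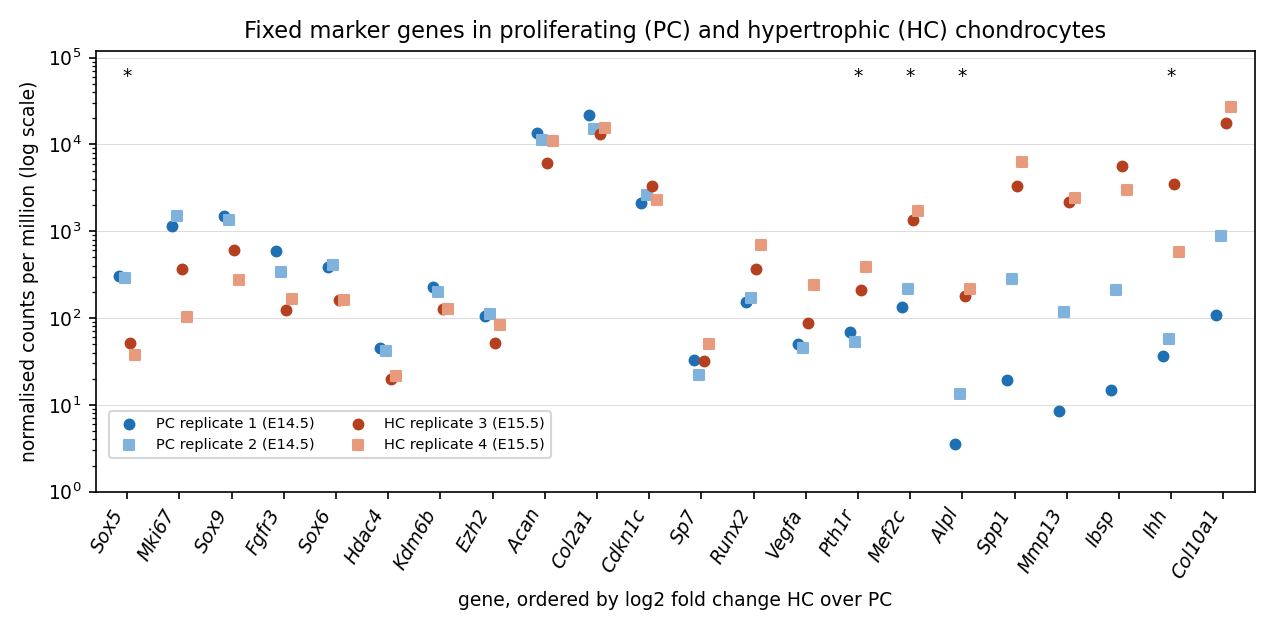
Normalised CPM (read counts scaled to a common library size, log axis) of the 22 genes named whatever their value, with 1 point per library, circles and squares for the replicates of a group, and an asterisk where the edgeR adjusted p was under 0.05. Col10a1 lies at 109 and 876 CPM in PC and at 17800 and 26920 in HC, while Col2a1 overlaps between the groups.

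Mineralisation genes rose in 4 of 22 cases and fell in 0, and adjusted over the list alone 11 rose and 2 fell. The 4 were Ank, Phex, Alpl and Phospho1, and 10 of the 22 genes are also in other lists. Without single libraries 8 to 12 mineralisation, 4 to 16 protease and 6 to 12 prehypertrophic genes were higher, and 5 to 15 sulphation genes were lower. The median was 1.17 (camera adjusted p = 2.51e-06, and adjusted p = 0.359 with an estimated correlation). Proteases and inhibitors of matrix remodelling had the same camera adjusted p, with 3 of 28 higher, 0 lower and a median of 1.34 (adjusted p = 0.359 with an estimated correlation). They were the collagen-degrading Ctsk (4.11 ± 0.56), the inhibitor Timp3 (2.17 ± 0.30) and Adamts9 (2.5 ± 0.42), and adjusted over the list alone 14 rose and 2 fell. Of 30 sulphation and glycosaminoglycan genes 6 fell and 1 rose, and adjusted over the list alone 12 fell and 3 rose. Without PC replicate 1, Phospho1, Timp3 and Slc35d1 did not pass (edgeR adjusted p = 0.16, 0.0598 and 0.078). The sulphate transporter Slc26a2 fell (-2.38 ± 0.39), as did Sulf2 (-2.44 ± 0.43) and Slc35d1 (-1.95 ± 0.36), while Sulf1 rose (3.51 ± 0.48). The median was -1.03 (camera adjusted p = 9.36e-05, and adjusted p = 0.365 with an estimated correlation).

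Genes of cell division that passed were all lower in HC, while most did not pass. Of 52 G2/M and mitosis genes 14 fell and 0 rose, and adjusted over the list alone 33 fell. Aurka fell from 33 and 28.3 to 2.27 and 1.53 CPM (-4.02 ± 0.43, edgeR adjusted p = 0.0359), and Ube2c, Cenpa and Birc5 by 2.79, 2.27 and 2.25 on the log2 scale. The proliferation marker Mki67 had a change of -2.48 ± 0.64 that did not pass (edgeR adjusted p = 0.0821), with -3.69 without HC replicate 3 and -1.89 without HC replicate 4. It had 366 CPM in HC replicate 3 and 104 in HC replicate 4. The median of the list was -1.93 (camera adjusted p = 5.83e-18, and adjusted p = 0.365 with an estimated correlation). Of 44 DNA replication genes 5 fell and 0 rose, and adjusted over the list alone 17 fell. Cdca7 (-4.47), Mcm5 (-2.54), Tipin (-2.26) and Dtl (-2.22) were among them, as was Cdc6 (-3.14), chosen after its values were seen. Their median was -1.24 (camera adjusted p = 6.52e-10, and adjusted p = 0.365 with an estimated correlation). Replication-dependent histones, whose near-identical copies share reads, had 11 of 30 lower and 0 higher, and adjusted over the list alone 25 fell. Hist1h4b, Hist1h2bb, Hist1h3b and Hist2h3b changed by -3.26, -4.33, -3.33 and -2.89. The histone median was -2.94 (camera adjusted p = 2.61e-15, and adjusted p = 0.365 with an estimated correlation). Without single libraries, 20 to 44 mitosis, 5 to 36 replication and 12 to 26 histone genes were lower, and Cdca7, Cenpa and Tipin did not pass without PC replicate 1 (edgeR adjusted p = 0.0972, 0.0537 and 0.113).

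Signalling lists held members that moved in opposite directions. In Hedgehog signalling, Ihh rose while Gli1, the co-receptors Boc (-3.52 ± 0.43) and Cdon (-2.70 ± 0.38) and Gli2 (-2.31, chosen after its values were seen) fell. These were 1 higher and 4 lower of 20, and adjusted over the list alone 3 and 7. The median was -0.74 (camera adjusted p = 0.0318, and adjusted p = 0.551 with an estimated correlation), and the camera adjusted p was 0.0587 without PC replicate 1, 0.612 without HC replicate 4 and 0.105 with a length offset, under which 1 gene was lower. Of 28 Wnt genes 5 rose and 3 fell, and adjusted over the list alone 6 rose and 10 fell (camera adjusted p = 0.92, median -0.37). The secreted antagonists Wif1 (3.97 ± 0.36) and Frzb (3.36 ± 0.40) and the receptor Lgr6 (4.18 ± 0.60) rose, and the receptor Fzd9 fell (-3.48 ± 0.55). Wnt5b and Tcf7l2 also rose, and Fzd1 and Sfrp2 fell; Wnt5b, Tcf7l2 and Fzd1 were chosen after their values were seen. BMP and TGF-beta genes had 3 of 35 higher (Bmp6, Bmp2 and Tgfb1) and 0 lower, and adjusted over the list alone 8 higher and 6 lower (camera adjusted p = 0.436). The median of that list was -0.01 and its mean -0.03, while camera placed it higher in HC. Of 21 FGF genes the receptor Fgfr1 (2.79 ± 0.38) and Dusp6 (2.25 ± 0.40) rose, and the receptors Fgfr4 (-4.93 ± 0.65) and Fgfr2 (-1.81 ± 0.30) fell. Adjusted over the list alone 8 FGF genes rose and 7 fell (camera adjusted p = 0.293). Fgfr4 was at -5.873 without HC replicate 3 and -4.333 without HC replicate 4. Lgr6 and Fzd9 were at 3.609 and -2.812 without PC replicate 1 and 5.02 and -3.977 without PC replicate 2. Dusp6 and Sfrp2 did not pass without PC replicate 1 (edgeR adjusted p = 0.152 and 0.41) or PC replicate 2 (0.103 and 0.0637). The counts moved when PC replicates 1 and 2 and HC replicates 3 and 4 were left out in turn. Higher were 2, 2, 3 and 4 Hedgehog, 5, 5, 9 and 8 Wnt, 3, 3, 5 and 8 BMP and 2, 2, 7 and 10 FGF genes, and lower were 4, 4, 9 and 7, 2, 6, 12 and 13, 1, 2, 9 and 10, and 2, 4, 5 and 6 in the same order.

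Among regulators of chromatin, the theme of the series, 5 genes passed singly, and 0 of 4 lists passed with camera over all libraries. The lists held 29, 28, 40 and 14 genes tested. Their share of genes passing was near that of all genes, 782 of 16607, so the number sets these regulators apart in no way. No gene of 29 in the Polycomb repressive complexes passed, over all genes or adjusted over the list alone, and the list did not pass (camera adjusted p = 0.245, median -0.28). With edgeR, 0 of 29 were called, while leaving out HC replicate 4 gave 11 lower and 1 higher and a camera adjusted p of 0.0329, and the adjusted p was 0.691 with an estimated correlation over all libraries. Ezh2, the Polycomb methyltransferase, had a log2 fold change of -0.68 ± 0.34, and Bmi1 had 1.65 ± 0.34 (edgeR adjusted p = 0.273 and 0.0538). Ezh2 passed without HC replicate 4 (-1.13), and Bmi1 without HC replicate 3 or HC replicate 4. Of 28 histone acetylation genes 1 rose, the deacetylase Hdac9 (2.16 ± 0.34, edgeR adjusted p = 0.037), a call that was lost without PC replicate 1 (0.131) or PC replicate 2 (0.0798). Hdac4, a repressor of hypertrophy, had -1.09 ± 0.30 and did not pass (edgeR adjusted p = 0.0891), except without HC replicate 3 or HC replicate 4. Adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.838). Of 40 histone methylation genes 1 rose, the demethylase Kdm7a (2.48 ± 0.39), over all genes and adjusted over the list alone (camera adjusted p = 1). The demethylase Kdm6b had -0.75 ± 0.28 (edgeR adjusted p = 0.16). Among 14 DNA methylation genes, the dioxygenase Tet1 fell from 154 and 149 to 29.9 and 34.7 CPM (-2.23 ± 0.29, edgeR adjusted p = 0.0359). Mbd3 (-2.45 ± 0.45, with an edgeR adjusted p of 0.102 without PC replicate 1) and the maintenance methyltransferase Dnmt1 (-1.99 ± 0.37) also fell, 0 rose, and adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.0676). That list passed with library size alone (0.0378), without PC replicate 1 (0.0278) and without PC replicate 2 (0.0431), and had an adjusted p of 0.365 with an estimated correlation. Without HC replicate 3 there were 4 acetylation, 6 methylation and 1 DNA methylation genes higher and 3, 4 and 5 lower, and without HC replicate 4 there were 4, 1 and 1 higher and 7, 5 and 5 lower. Without PC replicate 1 there were 0 acetylation genes higher and 2 DNA methylation genes lower, and without PC replicate 2 there were 0 and 4. Without HC replicate 3 there were 2 Polycomb genes higher and 4 lower.

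Of 31 glycolysis and hypoxia genes the hypoxia factor Epas1 rose (4.05 ± 0.47) and the glycolytic enzymes Pgam1 (-1.94 ± 0.31) and Eno1 (-1.88 ± 0.33) fell. Adjusted over the list alone 2 rose and 7 fell. The median was -0.83 (camera adjusted p = 0.0064, and adjusted p = 0.374 with an estimated correlation), with 0.0723 without HC replicate 3. Of 30 genes of endoplasmic reticulum stress and secretion 1 fell, the transcription factor Creb3l2 (-2.35 ± 0.35). Its relative Creb3l1 had 4.30 ± 0.87 and did not pass (edgeR adjusted p = 0.0531), with 3.22 without HC replicate 3. Adjusted over the list alone 2 rose and 9 fell. The median was -0.71 (camera adjusted p = 0.00198, and adjusted p = 0.359 with an estimated correlation), with 0.0553 without HC replicate 4. Leaving out PC replicates 1 and 2 and HC replicates 3 and 4 in turn gave 2, 4, 12 and 13 glycolysis and 1, 4, 12 and 9 secretion genes lower, and 1, 1, 3 and 1 and 1, 1, 1 and 2 higher.

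Markers of osteoclasts, osteoblasts, vessels, red blood cells and macrophages also had medians above 0, alongside the hypertrophic, mineralisation and protease lists. Osteoclast markers had 4 of 11 higher and 0 lower (Ctsk, Acp5, Itgb3 and Car2), and adjusted over the list alone 10 higher, with a median of 3.76 (camera adjusted p = 4.1e-09, and adjusted p = 0.359 with an estimated correlation). Of 14 osteoblast and bone matrix markers, 9 of which are in other lists, 2 rose, among them Postn (2.35 ± 0.43), and 0 fell, and adjusted over the list alone 13 rose. Col1a1, the main collagen of bone, had 374 and 741 CPM in PC and 9312 and 3170 in HC and did not pass (edgeR adjusted p = 0.0529), with a log2 fold change of 2.48 without HC replicate 3. The osteoblast median was 3.13 (camera adjusted p = 1.01e-10, and adjusted p = 0.359 with an estimated correlation). Of 15 endothelial markers Cdh5 (4.38 ± 0.77), Flt1 (3.09 ± 0.57) and Kdr (3.56 ± 0.68) rose, and adjusted over the list alone 8 rose (median 3.01, camera adjusted p = 3.13e-06, and adjusted p = 0.365 with an estimated correlation). Cdh5 and Kdr were at 3.676 and 2.909 without PC replicate 1 and 5.666 and 4.661 without PC replicate 2. Of 11 red blood cell markers 4 rose and 0 fell, among them Hba-a2, Hbb-bt and Hbb-bs, which share reads with their copies, and adjusted over the list alone 5 rose (median 2.62, camera adjusted p = 2.7e-05, and adjusted p = 0.359 with an estimated correlation). Hbb-bt had 10.4 and 28.9 CPM in PC and 256 and 236 in HC. With 1 library left out at a time, medians ran from 1.79 to 3.13 for endothelial and 1.63 to 1.86 for red blood cell markers. They ran from 2.36 to 3.68 for osteoblast, 2.49 to 4.62 for macrophage and 3.22 to 4.24 for osteoclast markers. Without single libraries 5 to 11 osteoclast, 6 to 13 osteoblast, 3 to 12 endothelial and 2 to 11 macrophage markers were higher. Leaving out PC replicate 1 ended the calls of Car2, Postn, Flt1, Hbb-bs and Mrc1 (edgeR adjusted p = 0.0627, 0.0795, 0.078, 0.0612 and 0.421), and leaving out PC replicate 2 that of Mrc1 (0.312). Of 13 macrophage markers Mrc1 and Cd68 rose, and adjusted over the list alone 7 rose (median 3.25, camera adjusted p = 3.53e-05, and adjusted p = 0.39 with an estimated correlation).

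Of 19 skeletal muscle markers Myh3 and Myl1 rose, and adjusted over the list alone 6 rose (median 1.86, camera adjusted p = 2.51e-06, and adjusted p = 0.39 with an estimated correlation). Ttn had 6.25 and 10.4 CPM in PC and 262 and 52.1 in HC and did not pass (edgeR adjusted p = 0.0509), with a log2 fold change of 2.62 without HC replicate 3. Of 8 epidermis markers the junction genes Perp and Dsp rose, and adjusted over the list alone 3 rose (median 3.59, camera adjusted p = 0.000676, and adjusted p = 0.365 with an estimated correlation). Of 20 perichondrium, tendon and fibroblast markers Col5a2 (3.66 ± 0.39), Postn and Twist1 rose, and adjusted over the list alone 7 rose and 4 fell. Their median was 0.42 and their mean 0 (camera adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation), a call that was lost without PC replicate 1 (0.0736), PC replicate 2 (0.0528) or HC replicate 3 (0.447), and with a length offset (0.0577). Of 11 joint markers Cytl1 (-3.03 ± 0.39) and Sfrp2 (-3.86 ± 0.69) fell, and adjusted over the list alone 2 fell and 1 rose (camera adjusted p = 0.0701, median -0.69). The joint list passed without PC replicate 2 (0.0157, median -1.34), without HC replicate 4 (0.0428, median -1.20) and with a length offset (0.0394), had a median of 0.0 without PC replicate 1, and had an adjusted p of 0.469 with an estimated correlation. Of 12 nerve and Schwann cell markers 2 fell and 0 rose, among them Fabp7, at least 53.3-fold lower with 0 counts in HC, and adjusted over the list alone 5 fell and 2 rose (camera adjusted p = 0.433). Postn, Twist1 and Sfrp2 did not pass without PC replicate 1 (edgeR adjusted p = 0.0795, 0.314 and 0.41), nor Twist1, Sfrp2 and Fabp7 without PC replicate 2 (0.173, 0.0637 and 0.389). With PC replicates 1 and 2 and HC replicates 3 and 4 left out in turn, 6, 6, 9 and 15 muscle, 3, 3, 7 and 6 epidermis, 3, 4, 7 and 9 perichondrium, 0, 0, 1 and 1 joint and 0, 1, 2 and 3 nerve markers were higher. Lower were 0, 0, 2 and 0, 0, 0, 0 and 1, 1, 1, 6 and 4, 1, 1, 4 and 5, and 1, 0, 4 and 5 of them.

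**Figure D2:**
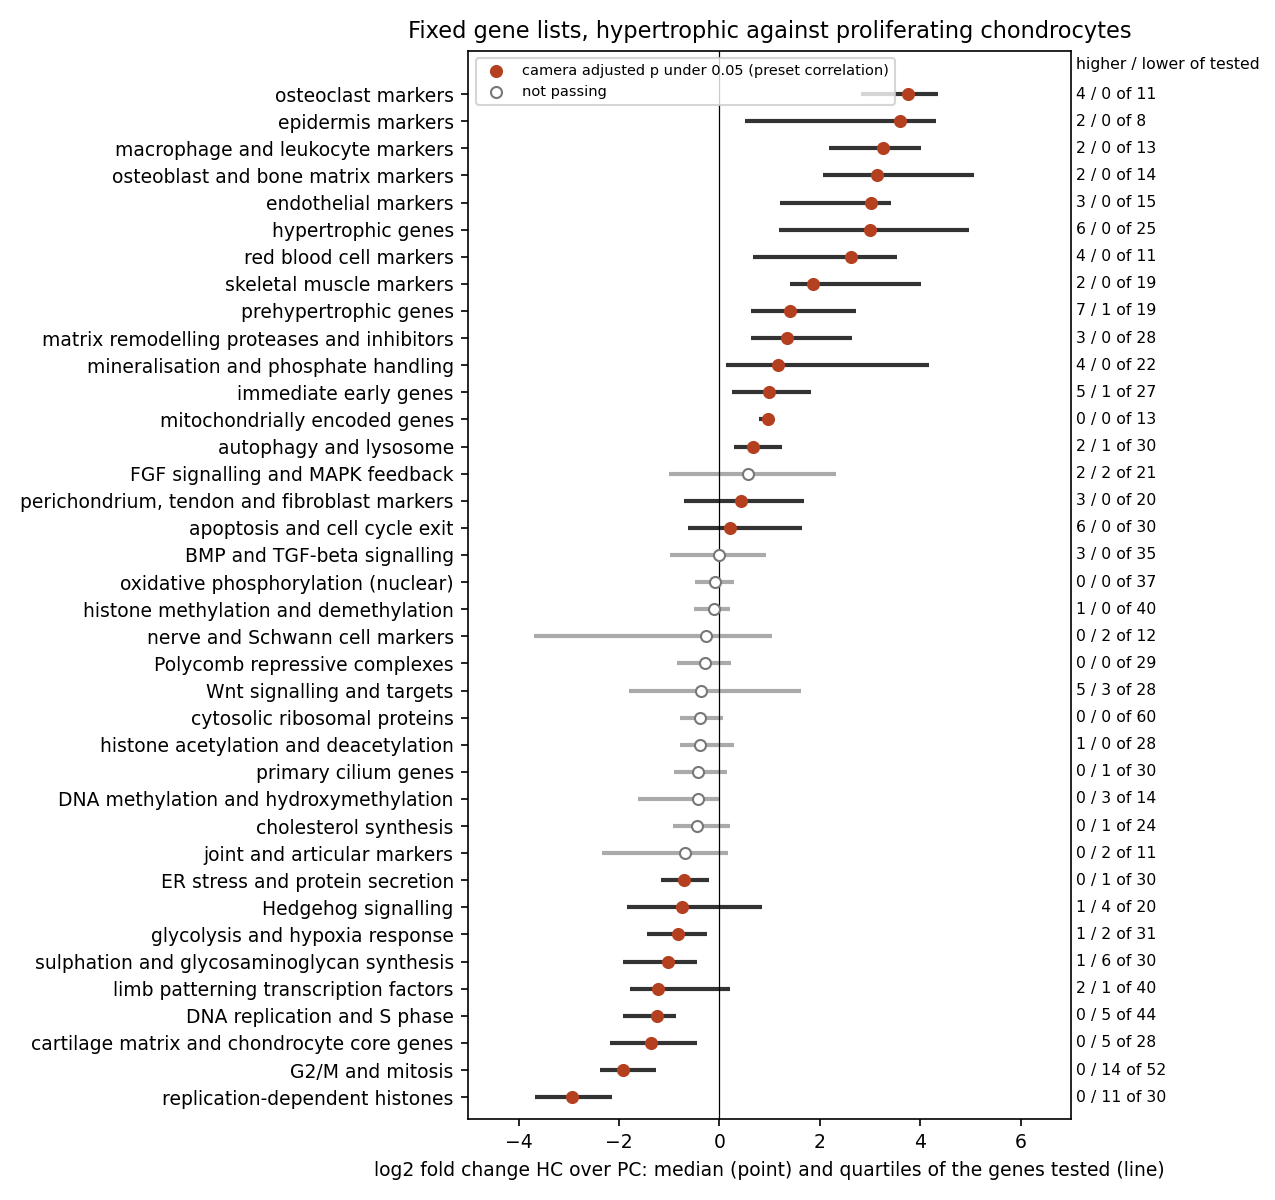
Median log2 fold change of HC over PC (points) and its quartiles (lines) for the genes tested in each of the 38 lists, with the number higher and lower over all genes at the right. Filled points had a camera adjusted p under 0.05 at a preset correlation. None passed with an estimated correlation, where 2 residual degrees of freedom left little room to pass. Medians run from -2.94 for replication-dependent histones to 3.76 for osteoclast markers.

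Transcript usage within genes was explored for 9183 genes. The likelihood test passed 3204 genes and the quasi-likelihood fit 16, and the simulated test at the real noise recovered 1% of changes, so these counts measure little. Col2a1-202 took 97.6% and 95.3% of the gene's estimated counts in PC and 99% and 99.1% in HC. Runx2-202 took 15.3% and 17.6% in PC and 29.5% and 32.7% in HC (adjusted p = 0.00141 with edgeR's likelihood test, 0.102 with its quasi-likelihood fit). Sox5-201 took 35.2%, 38.4%, 31.2% and 0%, and Fn1-203 63.5%, 53.3%, 4.2% and 45.2%, in PC replicates 1 and 2 and HC replicates 3 and 4. Pcbp2-201 took 75.3% and 63.8% in PC and 0% in both HC libraries, and Rab1a-206 took 0% in both PC libraries and 67.8% and 26.1% in HC (quasi-likelihood adjusted p = 0.0346 and 0.0103, edgeR). Gm15500-201 took 0% in PC and 20.1% and 18% in HC. Tpt1-205 took 0.4% and 55.8% in the PC libraries, and Plec-201 took 88.8% and 27.2% in the HC libraries.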

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

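Transcripts that matched no gene of the annotation lay outside every comparison and still held counts in each library. The share was largest in PC, at 0.53% of estimated counts, and 0.36% and 0.4% in HC. It was singled out because it lies above the limit that a count of 0 allows. The counts lay on the 1295 transcripts whose identifiers are absent from the annotation used, so the share follows from the matching step. It is no result about the cells.

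Of the tests below, the selection test, the depth test and the test of low counts were written before their results were seen, and the others only after. Genes far higher in HC also stood higher in PC replicate 2 than in PC replicate 1. Of 62 genes over 20-fold higher in both HC libraries than in PC replicate 1, 100% were higher in PC replicate 2, by a median of 3.8-fold. The excess had a median of 4.2% of the mean HC level, with quartiles of 3.4% and 5.0%. Choosing genes that chance made low in PC replicate 1 is argued against only weakly by the mirrored choice, where 0.0% of 6 genes were higher in PC replicate 1. These 6 were also among the 62 genes. Hypertrophic cells in the piece captured for PC replicate 2 may be the source. RNA or reads carried over from an HC library cannot be told apart from it, because only 3.8% of 78 genes for HC replicate 3 and 2.3% of 87 for HC replicate 4 lay clearly below a common fraction. Over 10744 genes PC replicate 2 was also nearer to HC replicates 3 and 4 (Pearson r 0.791 and 0.782) than PC replicate 1 was (0.687 and 0.703). Its mitochondrial share and effective lengths also lay between PC replicate 1 and the HC libraries. A part played by RNA quality was not tested.

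Fewer genes were detected in HC than in PC. Depth alone is argued against, since PC libraries thinned to the depth of HC replicate 3 still held at least 2247 more genes than either HC library. Fewer starting RNA molecules in HC may be the reason, but the test written for it cannot decide. Genes with 1 to 9 counts in HC were at most 43.5% of those in PC at equal depth, with 1854 and 2180 in HC and 5016 and 5024 in PC. At that depth 16900 and 17646 genes were detected in HC and 20282 and 20125 in PC. Fewer weakly counted genes therefore largely restate fewer genes detected. A true difference between the cell types, or in age, remains open and was not tested.

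Markers of blood, vessel, macrophage and osteoclast cells were higher in HC, with 92.0% of 50 genes above 0 and a median log2 fold change of 3.15, as were muscle (19 of 19 above 0, median 1.86), epidermis (7 of 8, 3.59) and osteoblast markers (14 of 14, 3.13). A lower share of chondrocytes would raise the other types, as in these lists. Perichondrium, tendon and fibroblast markers were not raised alike, with a median of 0.42, 12 above 0 and 8 below. As the whole source, a share that raises all types alike is argued against only weakly by 12 nerve markers, 6 of them above 0. Without HC replicate 3 the endothelial, red blood cell, macrophage and osteoclast medians were 1.79, 1.72, 2.49 and 3.31, and the nerve median -0.29. Over all libraries the nerve median of -0.27 (quartiles -3.7 and 1.05, and 0.18 without PC replicate 2) lay -3.42 from 3.15 (two-sided permutation test over genes, p = 4e-05), although 10 nerve markers had a mean TPM of at least 1 in PC. Nerve markers at that level in PC may not all stand for nerve. Joint markers all had that level, and cartilage itself expresses them, so they cannot test a lower share of chondrocytes. With them added, the difference was -3.82 over 22 genes (same permutation test, p = 2e-05, the smallest that 100000 permutations can give), which adds no support. The joint median was 0.0 without PC replicate 1. Both tests shuffled genes measured in the same 4 libraries, so their p-values measure no spread between samples. Low counts are argued against too, since the median of 3.15 stood at percentile 100 of 10000 random lists matched on expression, whose middle 95% ran from -0.42 to 0.40. Cells of these types in the captured HC pieces may be the source. Levels in HC were 256 and 236 CPM for Hbb-bt and 164 and 80.8 for Ctsk, and far higher for Col1a1, as given above. Expression by the chondrocytes themselves, and age, remain open and were not tested. A mean TPM of at least 1 in PC was found for 7 of 15 endothelial, 8 of 11 osteoclast, 8 of 11 red blood cell and 6 of 13 macrophage markers. The same held for 11 of 19 muscle, 12 of 14 osteoblast and 1 of 8 epidermis markers. A marker near 0 in PC could enter the tests only through its HC counts, which favours values above 0.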

How the results depend on the processing

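No called gene changed sign in any alternative fit that tested it, which shows little, since the groups were apart in all 782. No paired analysis was possible because the groups share no replicate number. Leaving out a library leaves 1 against 2, a fit that takes its noise from the remaining pair and assumes that the lone library varies alike. The log2 ratios between the PC libraries had a standard deviation of 0.54, and those between the HC libraries 0.99. More calls without an HC library are therefore no sign of a firmer result. More calls with DESeq2 or limma-voom may hold more false ones. On the simulated counts DESeq2 called 55 unchanged genes beside 67.5% of the 200 changed ones, and limma-voom 13 beside 42.5%. The edgeR test called 10 unchanged genes there. The numbers higher and lower in HC, 457 and 325, became 963 and 965 with no filter, 827 and 581 with at least 50 counts, 268 and 165 with a length offset, 1651 and 1446 with DESeq2, and 994 and 923 with limma-voom. They were 0 and 0 with library size alone, with limma-trend and at a threshold of 0.01, and 1184 and 1236 at 0.1, which was chosen after seeing the data. Without single libraries they ranged from 379 to 3331 higher and from 257 to 3775 lower. The share of higher calls was 58.4%, and 46.2% without HC replicate 3. Genes passing the 2-fold test, 0, became 882 with no filter, 402 with at least 50 counts, 488 at 0.1, and 286 to 3930 without single libraries. Of 38 lists 25 passed, 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.0797), and 22 to 27 without single libraries. Genes with changed transcript usage, 3204, became 1660 with at least 50 counts, 1727 for protein-coding transcripts, 16 with the quasi-likelihood fit and 13 to 4924 without single libraries.

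Cdkn1c turned from 0.23 to -0.057 with library size alone, -0.39 with limma-trend, and ranged from -0.10 (without HC replicate 3) to 0.43 without single libraries, and the other 174 of 175 named genes kept their sign in those of 15 alternatives that tested them, of which 4 tested 171 to 174 of the 175. Of 109 named genes that passed, 27 lost the call without 1 library, all of them without a PC library. Lists far from passing also turned: Wnt (camera adjusted p = 0.956, length offset), BMP and TGF-beta (0.709 to 0.893 without single libraries, turned without HC replicate 3) and oxidative phosphorylation (0.946, at least 50 counts). So did histone acetylation (0.862 with a length offset, 0.334 to 0.859 without single libraries, turned without HC replicate 3) and histone methylation (0.969 with DESeq2 size factors, 0.843 with at least 50 counts, 0.571 with a length offset, 0.334 to 0.844 without single libraries, turned without HC replicate 3 at 0.597). Of the named genes, 32 lost their call with a length offset, 109 with library size alone and 108 with limma-trend. The cause of these changes was not tested, except for 3 plain effects of the settings. A filter changes how many genes are tested, a lower threshold how many pass, and a left-out library which pair sets the noise. Depth limits genes near 0 in HC, the shallower group.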

Other observations

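Immediate early genes respond quickly to signals and to handling of tissue, and most of those that passed were higher in HC. Of 27, 5 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell. Egr1 went from 7.21 and 12.6 to 166 and 162 CPM (4.05 ± 0.40, edgeR adjusted p = 0.0359), and Atf3, Egr3 and Egr2 rose by 4.63, 4.55 and 4.72 on the log2 scale. Klf6 rose (1.82) and Myc fell (-2.25), both chosen after their values were seen. The median was 0.99 (camera adjusted p = 1.04e-05, and adjusted p = 0.359 with an estimated correlation). Among 30 apoptosis and cell cycle exit genes 6 rose and 0 fell, and adjusted over the list alone 7 rose. They include Cdkn1a, the retinoblastoma gene Rb1 (2.34 ± 0.33) and Bcl2l11 (2.64 ± 0.44). The list had a camera adjusted p of 0.0142, 0.0662 without PC replicate 2, 0.334 without HC replicate 4, and an adjusted p of 0.39 with an estimated correlation. Of 30 autophagy and lysosome genes Mitf (3.14 ± 0.43) and Map1lc3b (2.04 ± 0.33) rose and Hexa fell (-2.05 ± 0.39), and adjusted over the list alone 7 rose and 1 fell. That list had a camera adjusted p of 0.000525, 0.134 without HC replicate 4, and an adjusted p of 0.472 with an estimated correlation. Rb1 and Hexa did not pass without PC replicate 1 (edgeR adjusted p = 0.0547 and 0.0859), nor Map1lc3b without PC replicate 2 (0.0556). Across fits without PC replicates 1 and 2 and HC replicates 3 and 4 in turn, 5, 6, 14 and 11 immediate early, 2, 3, 10 and 9 apoptosis and 2, 2, 9 and 8 autophagy genes were higher, and 0, 2, 2 and 2, 0, 0, 3 and 7, and 0, 1, 2 and 3 lower.

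Among 40 limb patterning transcription factors, Irx3 (4.92 ± 0.44) and Irx5 (5.26 ± 0.81) rose and Hoxa11 fell (-3.20 ± 0.61), and adjusted over the list alone 3 rose and 2 fell. Irx3 had 0.843 and 1.17 CPM in PC and 30 and 31.2 in HC. The list's median was -1.23 (camera adjusted p = 0.037, 0.176 without HC replicate 4, 0.0526 with at least 50 counts, and adjusted p = 0.365 with an estimated correlation). Without PC replicates 1 and 2 and HC replicates 3 and 4 in turn, 2, 2, 5 and 6 limb factors were higher and 0, 3, 17 and 18 lower. All 13 mitochondrially encoded genes had positive log2 fold changes, with a median of 0.97, and 0 passed singly with edgeR or adjusted over the list alone. Their camera adjusted p was 0.00278, 0.243 without HC replicate 3, and the adjusted p was 0.48 with an estimated correlation. The nuclear genes of oxidative phosphorylation had a median of -0.08, and 0 of 37 passed over all genes or adjusted over the list alone (camera adjusted p = 0.924). No ribosomal protein gene of 60 passed over all genes or adjusted over the list alone (median -0.38, camera adjusted p = 0.0701, 0.03 with library size alone, 0.00218 without PC replicate 2, 0.0385 without HC replicate 3, and adjusted p = 0.6 with an estimated correlation). Ribosomal genes had 3 lower without PC replicate 2, 2 lower without HC replicate 3, and 13 lower and 5 higher without HC replicate 4. Among cholesterol synthesis genes 1 of 24 fell, Dhcr7 (-1.50 ± 0.29), and 0 adjusted over the list alone (camera adjusted p = 0.245, 0.0258 without PC replicate 2, and adjusted p = 0.746 with an estimated correlation). Among primary cilium genes 1 of 30 fell, Wdr35 (-1.68 ± 0.32), and 0 adjusted over the list alone (camera adjusted p = 0.168). Hoxa11, Dhcr7 and Wdr35 did not pass without PC replicate 1 (edgeR adjusted p = 0.097, 0.288 and 0.151) or PC replicate 2 (0.104, 0.0614 and 0.2). Leaving out HC replicate 4 gave 6 mitochondrial genes higher, 5 oxidative phosphorylation genes higher and 7 lower, 1 cholesterol gene higher and 7 lower, and 1 cilium gene higher and 8 lower. Leaving out HC replicate 3 gave 0 mitochondrial genes, 2 oxidative phosphorylation and 2 cholesterol genes lower, and 1 cilium gene higher and 8 lower. Leaving out either PC library gave 0 genes of these 4 lists.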
